A study of Mus musculus with 6 samples.

How the data were processed

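The deposited table covers RNA from whole hearts of 6 mice of strain C57BL/6 aged 2 months, 3 with a cardiac knockout of SRSF4 (floxed gene with Nkx2.5-Cre) and 3 controls (floxed gene without Cre), each heart from a separate animal per the labels. Per the labels' protocols, hearts were perfused with buffered saline and frozen, total RNA was extracted with a column kit, and cDNA libraries were made after poly(A) selection. Poly(A) selection favours polyadenylated RNA, so levels of other RNAs cannot be read from these libraries. The submitters' processing notes name cutadapt, Picard, RSEM 1.17, edgeR and the build GRCm38, with no role or order. The aligner, the annotation release, the filters and the use of strand are not given in the sources used here. The table has 12824 genes, so genes were selected before deposit.

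Per the file headers, the table gives raw values per library; they are whole numbers, and because the processing notes name RSEM, they are taken as the authors' estimated counts rounded to whole numbers before they were deposited. RSEM shares reads that match several genes among them by a model, so counts of near-identical genes and pseudogenes depend on each other. Per the file headers the authors also deposited normalized values, a signal equal to the counts of a library times 1 factor, their mean per group, and an overall mean. The deposited overall mean of this signal covers more libraries than the 6 used here. The authors' deposited comparison gives a log2 fold change of KO over control, a signed fold change (a score that is the negative reciprocal for lower genes), and a p-value with its adjusted value.

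Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, with TMM factors, the default low-count filter by group, a robust quasi-likelihood fit and the quasi-likelihood F test of genotype, all 6 libraries in 1 fit with no covariate. The filter removed 138 genes, 12 of them at 0 in all 6 libraries, and left 12686. Adjusted p is Benjamini-Hochberg's, with a threshold of 0.05; SE is the absolute log2 fold change divided by the square root of F. CPM uses the TMM-scaled library sizes, and log2 CPM a prior count of 2. The deposited totals ranged from 59810975 to 74941323 counts, and the common biological coefficient of variation was 13.6%. The same steps were tested on simulated data for 12629 genes in 1 seeded simulation. Of 94 genes changed 1.5-fold 38.3% were called, of 43 changed 2-fold 86.0% and of 63 changed 4-fold 96.8%, and 8.84% of the 147 calls were unchanged genes. The 94 include the 50 tested genes of the oxidative phosphorylation list, all raised, and the 63 a run of neighbouring genes. No outlying library was simulated, so these shares need not hold for the real libraries.

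Gene lists of heart programmes, RNA processing and cell type markers were fixed before the data were examined, as were the main test, the rule for named genes and most of the other settings tried. The 34 lists with at least 5 tested genes were tested with camera of limma 3.58.1, two-sided, at a preset correlation of 0.01, Benjamini-Hochberg over the 34. An estimated correlation and fry were run beside it. These test a shared direction of change. Fry's mixed test, which takes changes of either sign, is given for some lists. It does not compare a list with other genes, and many of the 34 lists passed it. Named genes were Srsf4, Nkx2-5, Gas5 and Nr3c1; the 10 called genes with the largest rise and the 10 with the largest fall, with a mean log2 CPM of at least 1, all KO values on one side of the controls, and predicted genes and pseudogenes passed over; the 4 members with the smallest p of each list that passed camera or had at least 2 called members, and at most 2 called members of other lists; and Nppa, Nppb, Myh6, Myh7, Acta1, Fkbp5, Per1 and Tsc22d3. A few genes that the rule takes are not reported here.

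The other settings fixed beforehand were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-trend, limma voom with sample quality weights, no filter, a filter of CPM of at least 1 in at least 3 libraries, the heart number as a block, leaving out each library in turn, an adjusted p of 0.01, and a 2-fold limit. Chosen after the data were seen were the authors' scaling factors, leaving out pseudogenes and genes with a near-identical copy, leaving out intervals with an excess of calls, summing counts over copies, and leaving Srsf4 or Gas5 out of its list. The 10 splits of the 6 libraries into groups of 3 were each fitted once.

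Near-identical copies were found by aligning the longest transcript of each gene of the table in GENCODE M21 with blastn 2.17.0: at least 90% identity, alignments of at least 60 bases, 200 bases in all and 50% of the shorter transcript, which gave 712 genes in 294 families. This definition was set after the data were seen and widened because known pairs such as Gapdh and its pseudogene were missed by a narrower one; Gm6768 and Gm9825 still have no copy under it. Families join genes through chains of matching pairs, so the members of a family need not all match each other. The family of Bzw2, for example, also holds Xdh, Ppp2r5a and predicted genes. The main copy of a family is its member other than a pseudogene with the highest mean CPM in controls. The 10-Mb intervals with at least 20 tested genes, the limits of 10 and 100 counts and the windows of 5 Mb were also set after the data were seen. Intervals were tested with a one-sided hypergeometric test of the number called, Benjamini-Hochberg over 215. Neighbouring called pairs were compared with 10000 permutations of the calls along chromosomes 1 to 19 and X. Coordinates are those of the table, on GRCm38 as the processing notes name it: 12761 of 12824 gene IDs are in GENCODE M21, and 99.9% of those overlap its interval. Symbols missing from the table were filled from it by ID for 60 of 74 genes.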

Results

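RNA was sequenced from the hearts of 6 mice aged 2 months. In 3 of them the gene for the splicing factor SRSF4 carried loxP sites and was deleted by Cre recombinase driven by Nkx2-5, a transcription factor of cardiac muscle (knockout, KO). The other 3 carried the same floxed gene without Cre (control). SRSF4 is an SR protein, one of a family of RNA-binding proteins that act in splicing and in later steps of RNA life. The comparison addresses how the cardiac transcriptome differs when SRSF4 is removed from heart muscle, with attention to the non-coding RNA Gas5, the glucocorticoid receptor and cardiac hypertrophy, which are known themes of work on this gene in the heart. The estimated read counts summed to 74941323, 59810975 and 59814976 in controls 1 to 3 and to 73344126, 66927244 and 71234859 in KO hearts 1 to 3. At these totals 3 counts, the limit that a count of 0 allows, correspond to 0.0400 to 0.0502 CPM (counts scaled by library size), for counting error only. This limit leaves out the TMM factors that all other CPM values use. Levels below are mean CPM ± SD over the 3 hearts of a group.

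Srsf4 (ENSMUSG00000028911, chromosome 4, 131873617 to 131901706, GRCm38) was 2.36-fold lower in the KO hearts, at 9.77 ± 1.24 CPM against 23.1 ± 0.893 CPM (SD, n = 3 each). Single KO hearts had 10.8, 10.1 and 8.39 CPM and single controls 22.1, 23.5 and 23.7 CPM, so the libraries followed their labels. Its log2 fold change was -1.24 with a standard error (SE) of 0.11 (edgeR adjusted p = 0.000881). The count covers the whole gene and all cells of the heart, so it does not measure the deleted part alone. Nkx2-5 itself (ENSMUSG00000015579, chromosome 17, 26838664 to 26841565) was 1.93-fold lower, at 19.7 ± 1.13 CPM against 38.1 ± 1.75 CPM (edgeR adjusted p = 0.000652), and lies in a chromosome interval with an excess of called genes, described further on. Gas5 (ENSMUSG00000053332, chromosome 1, 161034422 to 161038539), a long non-coding host of small nucleolar RNAs that is known to bind the glucocorticoid receptor, was 16.7-fold lower. It had 0.968 ± 0.393 CPM in KO hearts and 16.3 ± 1.51 CPM in controls, a log2 fold change of -4.06 (SE 0.25, edgeR adjusted p = 0.000168). Gas5 overlaps the gene Zbtb37 in position, and strand use in the counting is not given. Reads from transcript sequence common to the pair may not be told apart, and how much they have in common was not measured. Nr3c1 (ENSMUSG00000024431, chromosome 18, 39410545 to 39491301), which encodes the glucocorticoid receptor, had 61.4 ± 7.89 CPM against 55.8 ± 4.85 CPM and did not pass the test (log2 fold change 0.14, SE 0.12, edgeR adjusted p = 0.558).

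**Figure D1:**
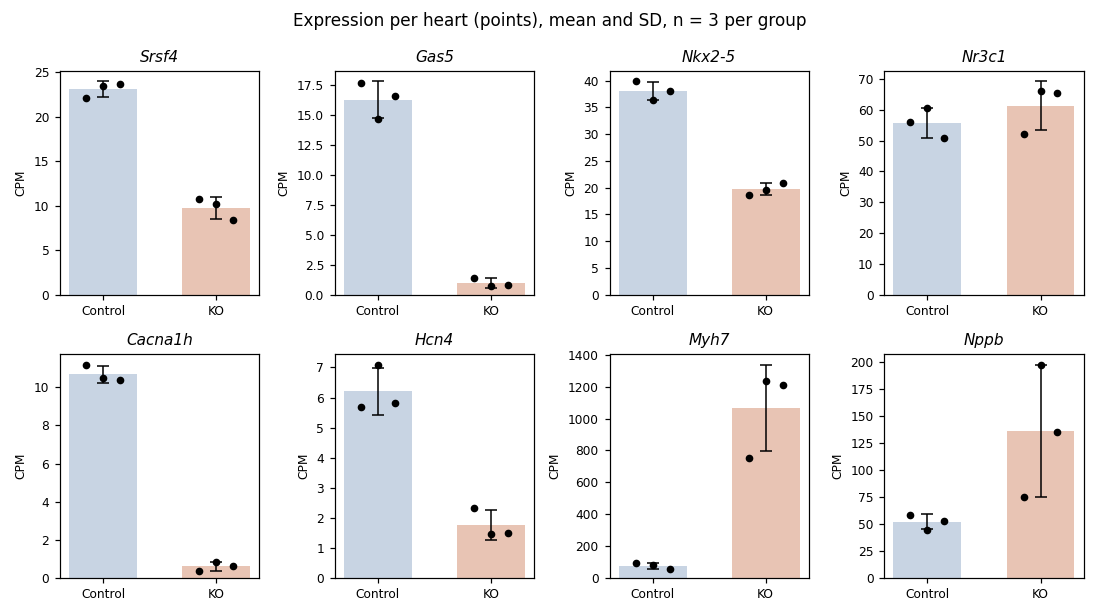
CPM of 8 genes in each heart (points), with bars for the group mean and error bars for the SD (n = 3 per group); each panel has its own vertical axis starting at 0. Srsf4, Gas5, Nkx2-5, Cacna1h and Hcn4 lie lower and Myh7 and Nppb higher in all 3 KO hearts, while the Nr3c1 values of the groups overlap.

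Of 12686 genes tested, 765 (6.03%) passed, 417 higher and 348 lower in the KO hearts, and 307 of them differed at least 2-fold (166 higher, 141 lower). In all 765 the KO values lay on one side of the control values, as they did in 27.2% of tested genes, where chance gives 10%. With total counts as the only scaling, which shifted the median log2 fold change of all genes from -0.0032 to -0.14, 1163 genes passed and 23.6% of them were higher in place of 54.5%. The first principal component (67.8% of the variance) separated the groups, and the second (17.4%) set KO 1, at -34.7, apart from KO 2 at 17.5 and KO 3 at 13.2. Leaving out 1 library gave 288 genes without control 1, 300 without control 2, 317 without control 3, 491 without KO 2, 426 without KO 3 and 2896 without KO 1. Every KO library has one library code prefix and every control another, so a library batch and the genotype cannot be told apart in any result given here.

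**Figure D2:**
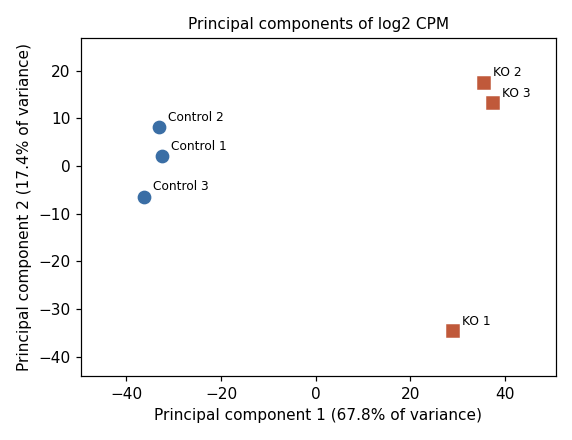
First and second principal components of log2 CPM, one symbol per heart (squares KO, circles control). Controls lie between -36.3 and -32.6 and KO hearts between 29.1 and 37.4 on the first component; KO 1 lies at -34.7 on the second.

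Among the 10 named genes with the largest increase, Myh7, the beta myosin heavy chain of the fetal and stressed ventricle, was 14.3-fold higher, at 1068 ± 271 CPM against 74.8 ± 17.5 CPM (edgeR adjusted p = 0.000249). It shares long stretches of sequence with Myh6, the dominant adult myosin, whose counts exceed those of Myh7 by far in these hearts, so that a sum over both does not test Myh7. Cpxm2, which encodes a carboxypeptidase-like protein, rose from 3.27 ± 0.429 to 45.8 ± 15.9 CPM (log2 fold change 3.81, SE 0.29, edgeR adjusted p = 0.00044). Baiap2l1, an adaptor of actin and membrane, rose 8.32-fold (from 9.24 ± 0.967 to 77.0 ± 4.73 CPM). Tmem37, a transmembrane protein related to calcium channel gamma subunits, rose 6.29-fold and Gnb3, a G protein beta subunit, 5.24-fold. The endosomal protein gene Wdfy1 rose from 3.30 ± 0.288 to 18.5 ± 1.71 CPM. Olfml2b, an olfactomedin-like gene, was 4.95-fold higher. The dynein light chain gene Dynlt1b was 9.27-fold higher and the splicing factor gene Cwc22 5.70-fold higher, and both stayed higher when counts were summed over their near-identical copies (log2 fold changes 1.71 and 2.81). Ly6c2, a surface antigen of monocytes, was 5.64-fold higher, at 6.19 ± 0.399 against 1.09 ± 0.199 CPM. This value is uncertain, because its near-identical neighbour Ly6c1 had 75.5 ± 4.56 against 105 ± 6.77 CPM and can share reads with it.

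Among the 10 with the largest decrease, Cacna1h (ENSMUSG00000024112, chromosome 17, 25374285 to 25433783), a T-type calcium channel subunit, was 18.0-fold lower, at 0.596 ± 0.234 CPM against 10.7 ± 0.450 CPM (log2 fold change -4.17, SE 0.25, edgeR adjusted p = 0.000161). Gas5, given above, followed. Ogdhl, an enzyme related to the oxoglutarate dehydrogenase of the citric acid cycle, was 9.38-fold lower (14.7 ± 8.24 against 137 ± 17.8 CPM). Hsd17b7, an enzyme of cholesterol synthesis, was 8.32-fold lower. Hmga1, a chromatin protein, was among them too, but its reads can be shared with near-identical sequence, and its fold is not given here. Hjurp, a chaperone of centromeric histone, was 6.44-fold lower, the collectin gene Colec11 6.15-fold lower and Nab1, a corepressor of EGR transcription factors, 5.91-fold lower. Nrn1, encoding neuritin, was 5.76-fold lower (edgeR adjusted p = 0.0182) and lost its call without control 1, KO 1 or KO 3 (edgeR adjusted p 0.0544 to 0.0698). The other 19 of these 20 genes were called in all 6 fits that left out a library. In all, 6 of the 20, among them Dynlt1b, Olfml2b, Cacna1h, Hmga1 and Colec11, lie in the intervals with an excess of called genes, and 16 predicted genes or pseudogenes with larger increases were passed over by the rule for named genes.

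The 12 tested SR protein genes fell as a list (camera adjusted p = 0.0218; with an estimated correlation adjusted p = 0.699). Of them 1 rose and 2 fell, and 1 rose and 5 fell when adjusted over the list alone; the median log2 fold change was -0.23. Srsf6 was 1.34-fold higher (54.2 ± 1.52 against 40.6 ± 1.66 CPM, edgeR adjusted p = 0.0154), Srsf1 was 1.24-fold lower (edgeR adjusted p = 0.0494), and Tra2a, at 13.4 ± 1.14 against 16.9 ± 0.143 CPM, did not pass (edgeR adjusted p = 0.0718). Because Srsf4 is the deleted gene, it is not independent evidence of the list's direction; without it the camera adjusted p was 0.0459. Srsf1 kept its call only without KO 1, and Srsf6 only without KO 1 or KO 3. The Srsf6 call was also lost with total counts (edgeR adjusted p = 0.0538), and the Srsf1 call with RLE factors (0.0541), with the authors' factors (0.0516), without genes with a copy (0.0546) and without the intervals with an excess of calls (0.0535).

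The 16 tested hosts of small nucleolar RNAs and other non-coding RNAs of this class also fell as a list (camera adjusted p = 0.0459; with an estimated correlation adjusted p = 0.724). Only Gas5 and Snhg6 passed the gene test, 2 also when adjusted over the list alone. Snhg6 had 0.800 ± 0.200 CPM against 4.51 ± 0.551 CPM, 5.62-fold lower (edgeR adjusted p = 0.000629). The transcripts 9430008C03Rik, named Snhg17 in the reference annotation, and Snhg18 had log2 fold changes of -0.44 and -0.30 and did not pass. Without Gas5, the gene for which this list was drawn up, the camera adjusted p was 0.169. The list's call was also lost without control 3, KO 2 or KO 3 (camera adjusted p = 0.104, 0.124 and 0.169) and with total counts (0.192). Over all settings it ranged from 0.00104 to 0.724.

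Glucocorticoid receptor targets did not move in a shared direction as a list (camera adjusted p = 0.671), with a median log2 fold change of -0.22, a mean of 0.02 and a camera direction of down. For changes of either sign fry's mixed test gave an adjusted p of 0.00223. Here and for the lists below this test does not set a list apart, since many lists passed it. Among them were macrophage and monocyte (fry's mixed test, adjusted p = 4.07e-05) and neutrophil markers (0.000139), while fibroblast markers did not pass (0.733). Of 29 tested targets 2 rose and none fell in edgeR's test, over all genes or over the list alone. At an unadjusted p under 0.05 edgeR had 9 of them, and DESeq2 called 4, limma-trend 2 and voom 7. Ptgds, a prostaglandin D synthase, rose 4.38-fold to 315 ± 89.7 CPM from 71.9 ± 3.48 CPM (edgeR adjusted p = 0.00146). Cdkn1a, the cell cycle inhibitor p21, rose 2.29-fold (20.8 ± 2.27 against 9.08 ± 1.62 CPM, edgeR adjusted p = 0.00395) and lies in an interval with an excess of called genes. Both were called in all 6 fits that left out a library. Classical targets did not pass: Fkbp5, which lies in such an interval too, had 42.7 ± 6.76 against 32.1 ± 9.71 CPM, Per1 23.9 ± 8.95 against 40.2 ± 10.5 CPM and Tsc22d3 57.5 ± 11.7 against 78.3 ± 17.1 CPM (edgeR adjusted p = 0.348, 0.22 and 0.254). Sult1a1 and Lcn2, next by p, had log2 fold changes of -0.36 and 1.24. In the receptor's own axis 1 of 10 genes rose, the chaperone Hsp90aa1 (106 ± 14.3 against 70.8 ± 3.59 CPM, edgeR adjusted p = 0.0262, kept only without KO 1), also 1 over the list alone, and the list did not pass (camera adjusted p = 0.263).

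Genes of hypertrophy and the fetal programme rose as a list (camera adjusted p = 0.0459; with an estimated correlation adjusted p = 0.699). Of 20 tested, 4 rose and none fell, against 8 and 2 when adjusted over the list alone. Beside Myh7 these were Rcan1, a calcineurin regulator and target (57.8 ± 7.47 against 37.8 ± 2.20 CPM, 1.53-fold), the stress cytokine Gdf15 (1.38 ± 0.538 against 0.450 ± 0.154 CPM, 3.03-fold) and the natriuretic peptide Nppb (136 ± 61.0 against 51.9 ± 6.84 CPM, 2.62-fold, edgeR adjusted p = 0.0469). Rcan1, Gdf15 and Nppb kept their calls only without KO 1 (edgeR adjusted p 0.0504 to 0.163 in the fits that lost them). The Nppb call was also lost with limma-trend (adjusted p = 0.0594), and those of Nppb and Gdf15 without the intervals with an excess of calls (edgeR adjusted p = 0.0535 and 0.0514). Nppa, the atrial natriuretic peptide, did not pass (edgeR adjusted p = 0.791), with 39.6 CPM in KO 1, 237 in KO 2, 185 in KO 3 and 193 ± 31.7 CPM in controls; its log2 fold change of -0.32 became 0.13 without KO 1. Acta1, the skeletal actin, had 342 ± 323 against 194 ± 29.3 CPM and did not pass (edgeR adjusted p = 0.472), with a log2 fold change of 0.82 that became -0.31 without KO 2. The list's call was lost without KO 2 (camera adjusted p = 0.253) and without pseudogenes and genes with a copy, Myh7 among them (camera adjusted p = 0.104). Over all settings it ranged from 0.00241 to 0.699.

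Sarcomere genes did not move in a shared direction as a list (camera adjusted p = 0.517, median log2 fold change -0.06, mean 0.08). For changes of either sign fry's mixed test gave an adjusted p of 0.000615. Of 25, Myh7 rose and Myom1, the M-band protein myomesin, fell (853 ± 53.4 against 1140.2 ± 75.3 CPM, edgeR adjusted p = 0.0437, kept only without KO 1), the same numbers as over the list alone. Tcap and Tpm1 had log2 fold changes of -0.61 and -0.29 and Myh6 of 0.08, without passing. Of 31 genes of calcium handling and excitation 1 rose and 4 fell, against 2 and 6 over the list alone. The list did not pass in a shared direction (camera adjusted p = 0.624, median 0.02, mean -0.25, direction down), and fry's mixed test gave an adjusted p of 4.07e-05. Hcn4, the main pacemaker channel, was 3.51-fold lower (1.76 ± 0.494 against 6.20 ± 0.773 CPM, edgeR adjusted p = 0.00271). Cacna1g, the other T-type calcium channel gene of the list, was 2.15-fold lower and lost its call without any 1 of the controls (edgeR adjusted p 0.0593 to 0.066). The kinase Camk2a was 1.33-fold lower and kept its call only without KO 1. Hcn2, chosen after its values were seen, was the gene that rose (log2 fold change 0.80, edgeR adjusted p = 0.0272, kept only without KO 1). Beside this, the 6 tested markers of the conduction system, which include Hcn4, fell as a list (camera adjusted p = 0.032; with an estimated correlation adjusted p = 0.699), with Hcn4 called over all genes, 3 called over the list alone and a median log2 fold change of -1.12. Cntn2 and Cacna2d2 had log2 fold changes of -2.36 and -0.49 and did not pass. The list's call was lost without control 2 (camera adjusted p = 0.0543), without KO 1 (0.132) and with total counts (0.115), and over all settings it ranged from 0.00805 to 0.699.

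Cardiac transcription factors did not move in a shared direction as a list (camera adjusted p = 0.953, median log2 fold change 0.05, mean -0.04, direction down). For changes of either sign fry's mixed test gave an adjusted p of 0.000101. Of 18, Nkx2-5 and Hey2 fell, against 1 higher and 2 lower over the list alone. Hey2, a repressor of atrial genes in the ventricle, was 1.81-fold lower (2.12 ± 0.103 against 3.84 ± 0.199 CPM, edgeR adjusted p = 0.0059). Srf and Hand2 had log2 fold changes of 0.27 and 0.47 and did not pass. Of 8 ventricular cardiomyocyte markers Hey2 alone fell, also over the list alone (camera adjusted p = 0.288). The 5 tested atrial markers fell as a list (camera adjusted p = 0.0459; with an estimated correlation adjusted p = 0.699), but only Stard10, a lipid transfer protein gene, passed the gene test, also over the list alone (9.23 ± 0.504 against 16.1 ± 0.503 CPM, 1.75-fold lower). Myl4, Nr2f1 and Nppa did not pass, and the list's call was lost without control 1 (camera adjusted p = 0.0612), without KO 1 (0.262) and with total counts (0.115), within a range of 0.0242 to 0.699.

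Mitochondrially encoded genes rose as a list (camera adjusted p = 5.12e-05; fry adjusted p = 0.0244; with an estimated correlation adjusted p = 0.699). Of 13, 3 rose over all genes and 9 over the list alone. The ATP synthase subunit mt-Atp6, which overlaps mt-Atp8 and mt-Co3, was 1.39-fold higher, and the complex I subunits mt-Nd2 and mt-Nd1 were 1.40-fold and 1.31-fold higher (edgeR adjusted p = 0.0194, 0.0247 and 0.027); all 3 kept their calls only without KO 1, and with total counts they also lost them (edgeR adjusted p = 0.0501, 0.0568 and 0.0785). A near-identical pseudogene of mt-Atp6 on chromosome 1, Gm10925, had more counts than mt-Atp6 itself, at 18689 CPM in KO hearts against 14067 CPM in controls. The sum over mt-Atp6 and Gm10925 was also higher (log2 fold change 0.43, edgeR adjusted p = 0.0232). The log2 fold change of mt-Atp8, 0.59, did not pass. All genes with a symbol starting with mt-, which can include mitochondrial ribosomal RNA genes beside these 13, took 31.9%, 30.9% and 30.8% of all counts in controls 1 to 3. In KO hearts 1 to 3 they took 32.8%, 36.2% and 36.3%. Gm10925 is not counted in these shares. Nuclear genes of oxidative phosphorylation fell as a list (camera adjusted p = 0.0459; with an estimated correlation adjusted p = 0.87), by a median log2 fold change of -0.10. Of 50, only Sdhc, a subunit of complex II, passed, also over the list alone (241 ± 31.1 against 381 ± 21.2 CPM, 1.58-fold lower). It lies in an interval with an excess of called genes and lost its call without any 1 of the controls or KO 3 (edgeR adjusted p 0.0654 to 0.0875). Sdha and Ndufv1 had log2 fold changes of -0.21 and -0.26 and did not pass. This list's call was lost without control 1, control 3, KO 2 or KO 3 (camera adjusted p = 0.0612, 0.328, 0.766 and 0.346), with total counts (0.0709) and without the intervals with an excess of calls (0.0586), and it was 1.02e-07 without KO 1. Glycolysis genes rose as a list (camera adjusted p = 0.0227; with an estimated correlation adjusted p = 0.699), 3 of 21 over all genes and 4 over the list alone. Pgam1, Hk1 and Pdk1 were 1.36-fold, 1.31-fold and 1.41-fold higher (edgeR adjusted p = 0.0169, 0.0319 and 0.0339) and kept their calls only without KO 1; with total counts these were also lost (edgeR adjusted p = 0.0503, 0.0857 and 0.0711). Pfkl, at 115 ± 10.2 against 89.0 ± 2.45 CPM, did not pass. The glycolysis call was lost without KO 1 (camera adjusted p = 0.262) and with total counts (0.0609), within a range of 0.00661 to 0.699. Of 29 fatty acid oxidation genes only Acadl fell, also over the list alone (1.30-fold, edgeR adjusted p = 0.034, kept only without KO 1; camera adjusted p = 0.924).

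**Figure D3:**
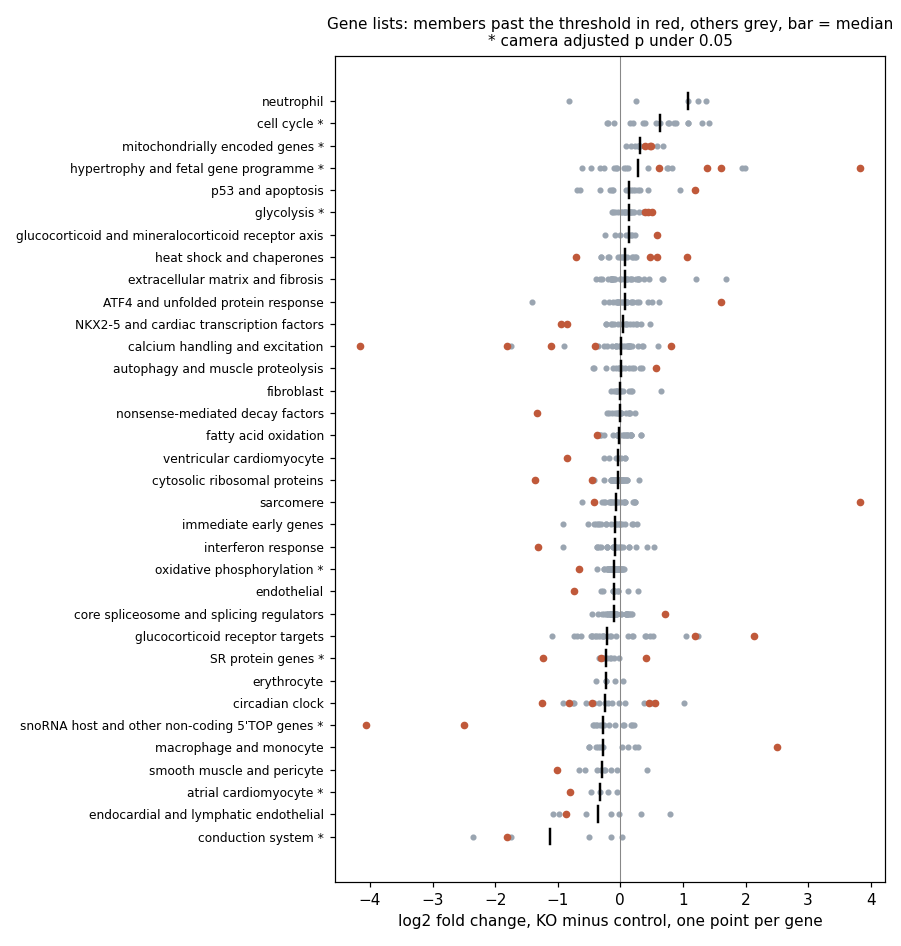
Log2 fold change (KO minus control) of every tested member of the 34 gene lists with at least 5 tested genes, with red points for genes past the threshold and black bars for list medians. Medians run from -1.12 in the conduction system to 1.08 in neutrophil markers; asterisks mark the 9 lists past camera's threshold with the preset correlation, none of which passed with an estimated correlation.

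Cell cycle genes rose as a list (camera adjusted p = 0.0218; with an estimated correlation adjusted p = 0.699), with a median log2 fold change of 0.64, but none of 17 passed edgeR's test, over all genes or over the list alone. At an unadjusted p under 0.05 edgeR had 7 of them, and DESeq2 called 3, limma-trend 0 and voom 7. Top2a had 2.04 ± 1.10 against 0.762 ± 0.178 CPM, Mki67 3.52 ± 2.07 against 1.67 ± 0.238 CPM, Prc1 a log2 fold change of 1.31 and Mcm3 of 0.39. The list's call was lost without KO 2 (camera adjusted p = 0.0531), within a range of 0.000664 to 0.699. Of 19 heat shock and chaperone genes 3 rose and 1 fell, against 4 and 2 over the list alone (camera adjusted p = 0.227). Hsph1, a cytosolic chaperone of the HSP110 family, was 2.08-fold higher (48.7 ± 1.56 against 23.4 ± 1.61 CPM, edgeR adjusted p = 0.00041) and Hspb1 1.39-fold higher. Hspa8 was 1.63-fold lower alone, and the sum over it and its near-identical copies did not differ (log2 fold change 0.20, edgeR adjusted p = 0.232); its own call was lost without control 1. Of 19 circadian clock genes 2 rose and 3 fell, against 3 and 8 over the list alone (camera adjusted p = 0.134). Nfil3 was 1.47-fold higher, Hlf and Cry2 1.76-fold and 1.36-fold lower, and Ciart, chosen after its values were seen, had a log2 fold change of -1.25 (edgeR adjusted p = 0.0461, kept only without KO 1 or KO 3). Hlf, Nfil3, Cry2 and Hspb1 each lost the call without at least 3 of the 6 libraries in turn. With total counts Nfil3 and Hspb1 lost it too (edgeR adjusted p = 0.0645 and 0.0707), and so did Cry2 with the authors' factors (0.0516) and without genes with a copy (0.0522).

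Of 17 nonsense-mediated decay factors only Rnps1, a protein of the exon junction complex, fell, also over the list alone (2.52-fold, log2 fold change -1.33, SE 0.09, edgeR adjusted p = 0.000278; camera adjusted p = 0.671), and it lies in an interval with an excess of called genes. Of 39 spliceosome genes and splicing regulators only Srpk2, an SR protein kinase, rose (1.63-fold, edgeR adjusted p = 0.0322), none over the list alone (camera adjusted p = 0.169). Its call was lost without any 1 of the controls or KO 3 (edgeR adjusted p 0.101 to 0.138). Of 48 ribosomal protein genes Rps7 and Rpl5 fell, also over the list alone (camera adjusted p = 0.227), while Rps7 summed with its copy did not differ (log2 fold change 0.01). Rpl5 kept its call only without KO 1, and its copy, which holds most counts of the pair, leaves its value uncertain. Rpl3 and Rplp1 had log2 fold changes of -0.27 and 0.30 and did not pass. Of 25 interferon response genes only Rsad2, an antiviral enzyme in an interval with an excess of called genes, fell, also over the list alone (2.49-fold; camera adjusted p = 0.27). Of 25 ATF4 and unfolded protein response genes only Gdf15 rose, none over the list alone (camera adjusted p = 0.27). Of 17 p53 and apoptosis genes only Cdkn1a rose, against 4 higher and 1 lower over the list alone (camera adjusted p = 0.207). Of 16 autophagy and proteolysis genes only Bnip3, a mitophagy receptor, rose, against 2 higher and 1 lower over the list alone (173 ± 5.93 against 116 ± 3.41 CPM; camera adjusted p = 0.454), and lost its call without control 1 (edgeR adjusted p = 0.0523). Neither the 32 extracellular matrix genes (camera adjusted p = 0.959) nor the 21 immediate early genes (0.227) held a gene past edgeR's test, over all genes or over the list alone. At an unadjusted p under 0.05 edgeR had 2 of the matrix genes and 0 of the immediate early genes; DESeq2 called 1 and 0, limma-trend 0 and 0, and voom 4 and 1.

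Markers of other cell types gave few calls. Acta2, the smooth muscle actin, was 2.02-fold lower (53.8 ± 2.83 against 109 ± 19.1 CPM, edgeR adjusted p = 0.00547), the 1 call among 10 smooth muscle and pericyte markers (camera adjusted p = 0.0722). The water channel gene Aqp1 was 1.67-fold lower (edgeR adjusted p = 0.00423), the 1 call among 12 endothelial markers (camera adjusted p = 0.207). Lyve1 was 1.83-fold lower, the 1 call among 8 endocardial and lymphatic markers, and 2 fell over the list alone (camera adjusted p = 0.288); its call was lost without control 1, control 2 or KO 3 (edgeR adjusted p 0.0788 to 0.0986). Among 12 macrophage and monocyte markers only Ly6c2 rose, whose value is uncertain as given above (camera adjusted p = 0.671; median log2 fold change -0.28, mean 0.04). The 5 tested neutrophil markers had a median log2 fold change of 1.08 without passing (camera adjusted p = 0.0571), none called by edgeR over all genes and 2 over the list alone; edgeR had 4 at an unadjusted p under 0.05, and DESeq2 called 1, limma-trend 0 and voom 3. No gene was called by edgeR among 12 fibroblast (camera adjusted p = 0.953) or 5 erythrocyte markers (0.395). At an unadjusted p under 0.05 edgeR had 1 and 0 of them, and DESeq2 called 1 and 0, limma-trend 0 and 0, and voom 2 and 0. In lists with fewer than 5 tested genes edgeR called no gene over all genes: the sex-linked genes (4 tested), platelet (4), Schwann and neuronal (4), skeletal muscle (4, with Tnni2, chosen after its values were seen, lower over the list alone), B cell and plasma cell (3), brown adipocyte (3), white adipocyte (1), thymus (1) and epicardial markers (1). Of these 25 genes edgeR had 5 at an unadjusted p under 0.05, and DESeq2 called 2, limma-trend 0 and voom 7. Markers of T and NK cells, lung and airway epithelium and valve were not analysed here.

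Pseudogenes were called more often than other genes. Of 105 tested pseudogenes 29 (27.6%) passed, 28 of them higher in KO hearts, against 5.78% of protein-coding genes (Fisher's exact test, two-sided p = 1.53e-12). Of 677 tested genes with a near-identical copy among the deposited genes, 103 (15.2%) passed, against 5.51% of the others. In all, 23 genes had at most 10 counts in each control and at least 100 in each KO heart, 10 of them pseudogenes and 19 with a copy. The reverse held for 1 gene, Gm28049, chosen after its values were seen. Among the 23, Gm13691, Gm13693, Gm13694, Gm13696, Gm13697 and Gm13698, also chosen so, are near-identical copies of Cwc22. Each had 0 counts in every control and the same 174, 112 and 111 counts in KO hearts 1 to 3, so they are not separate observations. The Gapdh pseudogene Gm13394, also chosen after its values were seen, had 10, 0 and 0 counts in controls and 14556, 27649 and 25116 in KO hearts, while Gapdh had a log2 fold change of -0.13 and did not pass.

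Called genes also lay next to each other more often than chance gives. Among genes in chromosome order 108 neighbouring pairs were both called, against a mean of 45.7 and a highest value of 69 in 10000 permutations (one-sided permutation p = 1e-04, the smallest they can give). In 8 of 215 intervals of 10 Mb more genes were called than elsewhere, 110 of 447 tested genes (24.6%) against 5.34% outside them. These lie on chromosome 1 at 150 to 160 Mb and 170 to 180 Mb, chromosome 2 at 80 to 90 Mb, chromosome 5 at 0 to 10 Mb, chromosome 7 at 90 to 100 Mb, chromosome 12 at 20 to 30 Mb and chromosome 17 at 0 to 10 Mb and 20 to 30 Mb. Without pseudogenes and genes with a copy, 5 of these kept an excess. Those on chromosome 2 and chromosome 5 did not (hypergeometric test, adjusted p = 1 and 0.519), and the one on chromosome 17 at 0 to 10 Mb, which holds Dynlt1b, had too few genes left to be tested. The interval on chromosome 17 at 20 to 30 Mb (adjusted p = 0.0119 without such genes) holds Nkx2-5, Cacna1h, Hmga1, Rnps1, Cdkn1a and Fkbp5.

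**Figure D4:**
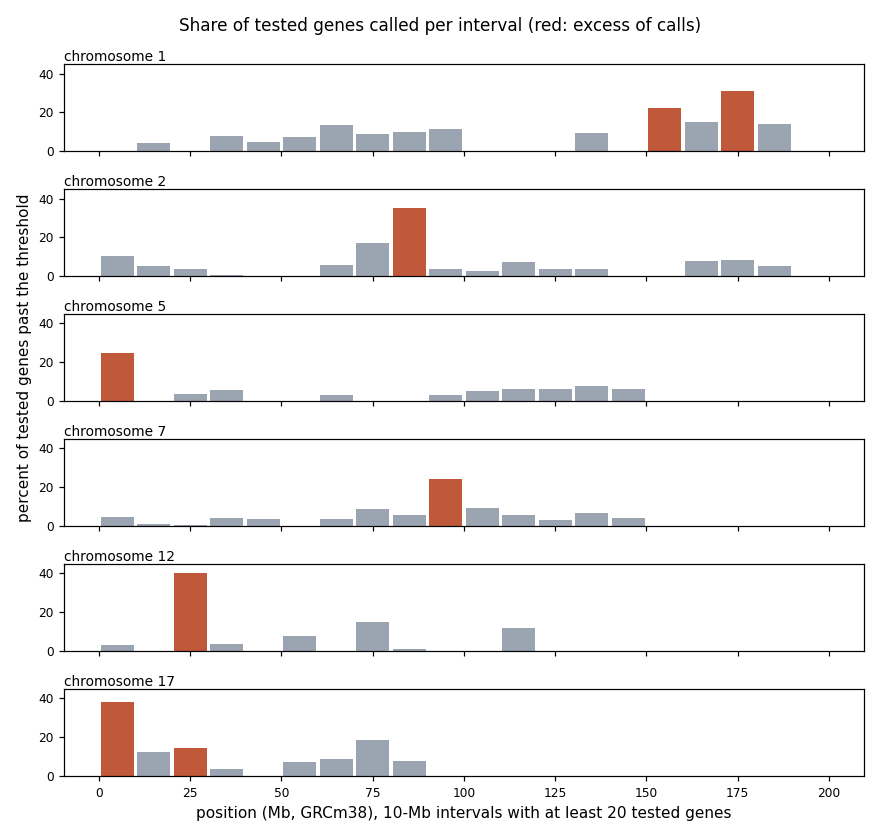
Percent of tested genes past the threshold in 10-Mb intervals (GRCm38) of the 6 chromosomes that hold an interval with an excess of calls (red); intervals with fewer than 20 tested genes were not tested and have no bar. The 8 red intervals reach 14.7% to 40.0%, against 5.34% of genes called outside them.

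The authors' deposited table called 825 genes at an adjusted p under 0.05 (438 higher, 387 lower). It called 580 (75.8%) of the 765 genes called here, all with the same sign. Its log2 fold changes correlated with those computed here across genes at r = 0.998 (genes are not independent replicates). Both start from the same counts, so the signs and the correlation check the computation and are not independent evidence. In the authors' deposited table Srsf4 had a log2 fold change of -1.24, Gas5 of -4.06 and Myh7 of 3.83. Single calls differed. For example, that table called Per1, Lcn2 and Cntn2 (authors' adjusted p = 0.00883, 0.000105 and 8.33e-05), which did not pass here. It did not call mt-Atp6, mt-Nd2, mt-Nd1, Rcan1 or Hspa8 (authors' adjusted p 0.0879 to 0.362), which passed here.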

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

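The values here come from a part of the deposited table that no comparison above uses, and they were looked at only after the data were seen. For 9 genes the authors' deposited overall mean lies above 1 although all 6 libraries have 0 counts. The highest are Rpl15-ps2, a ribosomal protein pseudogene, at 6.75 and Mup7, a major urinary protein gene of liver, at 4.16. The other 7 include the liver genes Serpina1c, Serpina3k and Fga, at 2.29, 1.90 and 1.32. An overall mean above 0 cannot come from 6 libraries at 0, so it covers libraries not analysed here. No biological explanation was tested. The groups of 3 hearts are small for a formal test of single outlying libraries, and none was made, though KO 1 stood apart as given above.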

How the results depend on the processing

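Of the settings below, the authors' scaling factors, the fits without copies or without intervals, the sums over copies and the lists without Srsf4 or Gas5 were chosen after the data were seen. Srsf4 was lower and called in every setting run, at a log2 fold change of -1.32 to -1.14 with 1 library left out. The count of called genes was 764 with RLE, 753 with upper-quartile, 759 with the authors' factors, 765 with limma-trend, 763 without a filter and 732 with the stricter filter. It was 1163 with total counts only (274 higher, 889 lower), 1468 with DESeq2 (833 higher, 635 lower) and 3547 with voom and sample quality weights (1875 higher, 1672 lower). It was 291 at an adjusted p of 0.01 (159 higher, 132 lower) and 307 with a 2-fold limit (166 higher, 141 lower). Without pseudogenes and copies it was 637, without intervals with an excess of calls 584 and with counts summed over copies 664. Leaving out 1 library gave 288 to 2896 genes, 154 to 1567 higher and 130 to 1329 lower. It turned the sign of none of the 765, which follows from their KO values all lying on one side of the controls. The unturned signs are therefore no separate support. The low end comes from fits with fewer samples; the highest value is without KO 1, which stands apart from the other KO hearts. Of the 61 called genes that the rule for named genes takes 33 kept their call in all 6 such fits and 17 only without KO 1.

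With the heart number as a replicate block 505 genes were called (261 higher, 244 lower), 475 of them also without it, and 10 lists passed. Nothing in the labels makes the number more than a name, and same-number deviations correlated at -0.06, 0.15 and -0.26. KO 1 and KO 3 correlated better with other controls (0.31 and 0.18), so the numbers were not taken as pairs.

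Lists past camera were 9 in the main setting, 9 with RLE, 5 with total counts only, 7 to 12 with 1 library left out, 0 with an estimated correlation (1 of 34 at an unadjusted p under 0.05) and 1 with fry. The overlap with the authors' deposited calls was 92.8% at an adjusted p of 0.01 and 51.6% with DESeq2, against 75.8%. Signs turned, in genes that passed nowhere, for Nr3c1 (-0.00084) and Myh6 (-0.058) with total counts only, for Nppa within -0.78 to 0.13 and for Acta1 within -0.31 to 1.19 with 1 library left out; the cause was not tested. Single genes were on the same side of the threshold in 1425 cases, weaker in 155, stronger in 46 and turned in 4; lists were the same in 89 and weaker in 39. At this depth and with 3 hearts per group, 38.3% of simulated 1.5-fold changes were found, so small changes can be missed. That simulation held no outlying library.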

Other observations

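The genotype tests behind the counts of called genes and lists were fixed before the data were examined; the tests of copies, neighbouring genes and windows and the counts over other splits were chosen only after the results were seen. Among non-coding classes edgeR called 22 of 192 tested long intergenic RNAs, 8 of them higher, 6 of 105 antisense RNAs, 2 of them higher, and 5 of 114 processed transcripts, none of them higher, Gas5 among these. Ptprn2, a phosphatase-like protein of secretory granules chosen after its values were seen, had 2, 4 and 4 counts in controls and 398, 470 and 850 in KO hearts, with no near-identical copy. Ifi202b, an interferon-inducible gene known to differ in expression between laboratory mouse strains and likewise chosen after its values were seen, had 0 counts in all 3 controls and 84, 106 and 134 in KO hearts.

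Splits of the 6 libraries into groups of 3, the real one included, number 10, so a share of them can never be under 0.1, and only values can be given. The real split called 765 genes and the highest other split 0, so 1 split called as many. At an unadjusted p under 0.05 edgeR had 2732 genes in the real split and 59 to 2721 in the others, the highest with controls 1 and 3 and KO 1 against the rest, which points to a structure of the samples beside the genotype; the other tools were not run on the other splits. The real split passed 9 lists and the highest other split 18, with 7 splits passing as many. The real split gave 108 neighbouring pairs among its top 765 genes and the highest other split 86, so 1 split gave as many; that other split, controls 1 and 3 with KO 3 against the rest, itself lies above the highest permuted value of 69.

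Pseudogenes were called in excess, 28 of the 29 called being higher in KO hearts, and 20 of them have a near-identical copy among the deposited genes. Reads shared between copies would lower the main copy where the pseudogene gains. Of 18 such main copies 12 were lower in KO hearts, against 165 of 273 in other families (Fisher's exact test, two-sided p = 0.804). This cannot decide, since most other main copies were lower too and some gains were small beside the main copy, so read sharing stays open. The sums over the 18 families had a median absolute log2 fold change of 0.22, against 8.57 for their called pseudogenes, and 3 were called. A small gain beside a large main copy gives the same. Single families went both ways, though not evenly. Of the main copies that passed the gene test, Hspa8, Ywhaz, Cox7a2l, Rpl21, Eif4a1 and Rps7 were lower in KO hearts, and Glo1 and mt-Atp6 higher. Rps7 lost 112 CPM and its pseudogene gained 113, while Glo1 rose with its pseudogene (log2 fold change 0.99). In 5 families, among them the chained family of Bzw2, the gain of the called pseudogenes was large enough to move the sum over copies by at least 3 SE. In 1 of these the sum lay closer to no change than to the gain. That gain leaves out copies of other classes, such as Gm26825 of the Hspa8 family (424 CPM in KO hearts against 0.405 in controls). A main copy that rose itself, such as Glo1, moves the sum too, so this count cannot decide. Of all 58 families with a called member 19 were called as a sum. A strain variant in the main copies gave no decision. Of 18 main copies 3 lay in the 5 intervals that kept an excess of calls without pseudogenes and genes with a copy, against 8 of 273 others (Fisher's exact test, two-sided p = 0.0241). These are too few to cover the pattern. A difference between library batches, such as another read length or reference, cannot be told apart from the genotype, because 0 library code prefixes occur in both groups.

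Called genes lay next to each other in excess. Reads shared between paralogs or pseudogenes are argued against as the whole cause, since 72 neighbouring pairs remained without pseudogenes and genes with a copy, above the highest permuted value of 61; among those at least 10 kb apart it was 48 against 47, a narrow margin. A candidate explanation is chromosome segments from another mouse strain that differ between the groups. It needs the real split to hold the most pairs, and its 108 exceed the highest other split (86). Among pairs at least 10 kb apart the margin was narrower, 67 against 59. Pairs without genes with a copy were not counted in the other splits. An effect of the genotype on neighbouring genes also needs the real split to hold the most pairs and stays open. No sequence variants can be read from gene counts, so the strain of these segments was not tested.

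Nkx2-5 was lower in KO hearts, and of 158 genes within 5 Mb of it 22 (13.9%) were called, 7 of them higher (Fisher's exact test, two-sided p = 0.000247, Benjamini-Hochberg 0.000494 over 6 windows tested). Around the floxed Srsf4, which both groups carry, it was 5 of 142 (3.52%), and around Myh7 4 of 105 (3.81%). This is consistent with the hypothesis that the chromosome around a Cre allele at Nkx2-5 differs between the groups, as Cre is carried by KO hearts only. Whether the Cre allele replaces a copy of Nkx2-5 or lies elsewhere is not given in the sources used here, and without Cre-only hearts an effect of Cre or of the lower Nkx2-5 cannot be separated from the loss of SRSF4. Cacna1h lies within this window (23 of 157 genes around it, 14.6%, were called), so for this gene the same hypothesis stays open beside an effect of SRSF4. Gas5 lies on chromosome 1, which this hypothesis does not cover, and the window around it held 9 called of 56 (16.1%, Fisher's exact test, two-sided p = 0.00586, Benjamini-Hochberg 0.00879). The highest share of the 6 windows was around Ifi202b, also on chromosome 1 and picked after its values were seen, with 26 of 79 called (32.9%), so an excess of calls is not particular to Nkx2-5.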
